A study of Mus musculus with 8 samples.

How the data were processed

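Single-cell RNA-seq had been run on sorted liver cells of 8 male C57BL/6J mice, with 1 library per mouse and 2 mice in each of 4 groups set by age and genotype. WT stands for Cx3cr1CreER;EP2wt/wt mice and cKO for Cx3cr1CreER;EP2lox/lox mice, in which the floxed gene is Ptger2, the gene of the prostaglandin E2 receptor EP2. Per the labels, all mice received tamoxifen at 4 to 6 months of age, and were studied at 6 to 8 months (young) or 23 to 25 months (aged). The labels name Cell Ranger 8.0.1, Seurat 5.2.0, R 4.3.2 and the genome build GRCm39 as the authors' tools, without saying which filters they applied. The deposited matrix holds raw UMI counts for 27398 genes in 126443 cells, merged over the 8 mice and with no normalization. All of its entries are whole numbers. The deposited cell table gives the sample name of each cell and no cell type. The deposited cells have 401 to 5498 detected genes and at most 24.99% mitochondrial UMIs. The libraries hold 71542613 to 123675312 UMIs each.

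Cells were grouped with scanpy 1.11.5 in Python 3.11.15. Counts were scaled to each cell's total and log-transformed, 2000 highly variable genes were chosen across mice (mitochondrial, ribosomal protein and immunoglobulin genes left out), and 40 principal components with 20 nearest neighbours went into Leiden clustering at a resolution of 1.5, with no integration over mice. Doublets were called per mouse with Scrublet at an expected rate of 8%. Clusters were named from marker genes of each cell type that were fixed before the data were examined, as were the groups, the 5 contrasts among them, the rule for which genes the text names, the gene lists and most of the alternative settings. The limits of the naming were set after the clusters had been seen, and before any groups were compared. A cluster needed 3 detected markers of its best type, a marker score of at least 0.45, at most 50% called doublets, and no more markers of another type than of its own among its 10 leading genes. It also stayed unnamed when more than 5 of its 10 leading genes led a cluster of another type with a higher marker score. The same held when its median UMIs lay under 1/3 of those of its mice and none of its leading genes was a marker of its type. Of 52 clusters, 40 received 1 of 16 names and 12 stayed unnamed, 7 of these because of doublets. The unnamed clusters hold 11656 cells, or 9.22% of all.

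Counts were summed over the cells of each mouse in 6 classes (Kupffer cells, neutrophils, monocytes, endothelial cells, T cells and B cells), with at least 20 cells per mouse. Genes past edgeR's filterByExpr were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on a 4-group model with TMM normalization, which leaves 4 residual degrees of freedom among mice. Ptger2 was always kept. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called past the threshold. All 5 contrasts were reported in Kupffer cells, and aged WT against young WT and aged cKO against aged WT in the other classes. Errors of log2 fold changes are standard errors derived from the test statistic. Where CPM (UMIs of the gene scaled to the total UMIs of the class in that mouse) is given for a gene, the library sizes were scaled by TMM, except where raw counts are named.

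After the gene counts of the 4-group model had been seen, 2 comparisons of 4 mice against 4 were added, all aged against all young and all cKO against all WT. They were first computed as averages over the 4-group model and then with a 2-group model, which has 6 residual degrees of freedom. The 2-group model was kept because the same model can be fitted to every other split of the 8 mice, and both forms and a form with the other factor as a covariate are given in the closing section.

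The genes named in the text are those with the smallest p-values among genes that passed the threshold with no overlap between the mice of the groups compared, plus up to 3 members from each fixed gene list with a member past the threshold. Where no gene passed, the 3 genes with the smallest p-values are given as not passing. Ptger2, Cx3cr1, Timd4, Mertk and Axl are given in Kupffer cells and Ptger2, Cxcr4, Cxcr2, S100a8 and Cdkn1a in neutrophils whatever their test. Not every gene that the rule selects is given in the text. Predicted and numbered genes were left out by the rule. Names beginning with AU, AI and ENSMUSG were also left out, which the rule as first written did not say. The text states where a gene was chosen after its values had been seen.

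Each fixed gene list with at least 5 tested members was tested against all other genes with camera of limma 3.58.1, at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Before these tests, entries of rounding size in the design matrix were set to 0, because the p-values of the estimated correlation and of fry had depended on the order of floating-point operations in 1 contrast. Members past the threshold are counted over all genes and again with p-values adjusted over the list alone. Several lists hold markers of other cell types, whose RNA could be carried into droplets as free RNA.

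Cell shares were tested as counts of 12 immune classes per mouse with edgeR, using all immune cells as the library size. Shares of cells with a Ptger2 UMI have 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Where a group has no counts of a gene, a floor of 3 counts over the group was used, and where it has 1 to 3 counts the ratio is given with its exact 95% interval. That interval pools the UMIs of the mice and leaves out the spread between them. Positions come from the GENCODE M21 annotation of GRCm38, an earlier build than the one named in the labels.

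The test was tried on simulated data with 200 changed genes, drawn only from tested genes above a minimum mean CPM. Recovery of genes with low counts was thus not tried, and genes were drawn independently of each other. The test also called 7 unchanged genes in Kupffer cells with 2 mice against 2 and 6 with 4 against 4. In T cells it called 17 and 13. In Kupffer cells with 2 mice against 2, it recovered 3% of genes changed 2-fold, 53.7% of those changed 4-fold and 92.4% of those changed 8-fold. With 4 mice against 4 it recovered 25.4%, 92.5% and 98.5%. In T cells with 2 mice against 2 the shares were 55.2%, 98.5% and 97%, and with 4 against 4 they were 91%, 97% and 97%.

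The alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, cells without called doublets, strict cells (at least 500 genes and at most 10% mitochondrial UMIs), a filter that keeps genes whose mean CPM in the class is at least 0.1 of their highest in any other class, the replicate number as a block, and leaving out each mouse in turn. With 1 mouse left in a group, its spread was taken to be that of the other groups. Deviations of mice from their group means correlated between same-numbered mice of different groups at −0.282 to 0.299, with mixed signs, so that replicate numbers were not treated as pairs. The labels also give each library a folder number, which runs consecutively within a group and differs between groups. Its meaning is not stated, and handling of the groups at different times cannot be told apart from the groups themselves. Figures were drawn with matplotlib 3.10.9.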

Results

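Liver cells of 8 male mice had been profiled by single-cell RNA-seq to ask how loss of the prostaglandin E2 receptor EP2 in Cx3cr1-expressing cells, which include tissue-resident macrophages, bears on the ageing liver and on the removal of senescent neutrophils by macrophages. The 4 groups of 2 mice each were young WT, aged WT, young cKO and aged cKO, and each mouse is named by its group and a number. The cells were non-parenchymal cells, sorted in equal parts as live CD45+, CD1d+ or CD31+ cells. Each mouse gave 12720 to 20959 cells, 71542613 to 123675312 UMIs and a median of 4130 to 5170 UMIs per cell. The median mitochondrial share of UMIs was 5.70% ± 0.389 (SD, n = 2) in aged WT, 7.10% ± 1.00 in aged cKO, 12.95% ± 0.870 in young WT and 12.99% ± 2.47 in young cKO mice. Cells of the young mice thus carried a higher mitochondrial share in every mouse. Kupffer cells, the resident macrophages of the liver, numbered 317 to 568 per mouse, with 1836122 to 5348555 UMIs in all.

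Ptger2, the gene of EP2 and the target of the deletion, had far fewer transcripts in neutrophils of cKO than of WT mice. It was detected in 0.277% (exact 95% interval 0.111 to 0.569) and 0.429% (0.214 to 0.766) of the neutrophils of the aged cKO mice and in 5.19% (3.95 to 6.67) and 4.35% (3.69 to 5.09) of those of the aged WT mice. The young mice had 0.781% (0.484 to 1.19) and 0.805% (0.548 to 1.14) with cKO against 5.38% (4.87 to 5.93) and 3.46% (2.78 to 4.26) with WT. In B cells, taken here as a background, the shares were 0.088% to 0.444%, from 1 to 13 Ptger2 UMIs per mouse. Whether B cells express the gene themselves was not tested. They had a median of 3014 to 5019 UMIs per cell against 2628 to 4195 in neutrophils. The aged cKO shares in neutrophils lay within the range of B cells. The log2 fold change of Ptger2 in neutrophils was −3.69 ± 0.423 (SE) in aged cKO against aged WT mice (adjusted p = 0.149 by edgeR) and −2.20 ± 0.371 in young cKO against young WT mice (adjusted p = 0.649). It was −2.79 ± 0.386 in all cKO against all WT mice (adjusted p = 0.0887), and lower in 4 of 4 cKO mice. None of these passed over all genes with all mice, but the aged comparison passed without WT_Aged_1 (−3.24, adjusted p = 0.00618) and without WT_Aged_2 (−4.07, adjusted p = 0.0113).

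**Figure D1:**
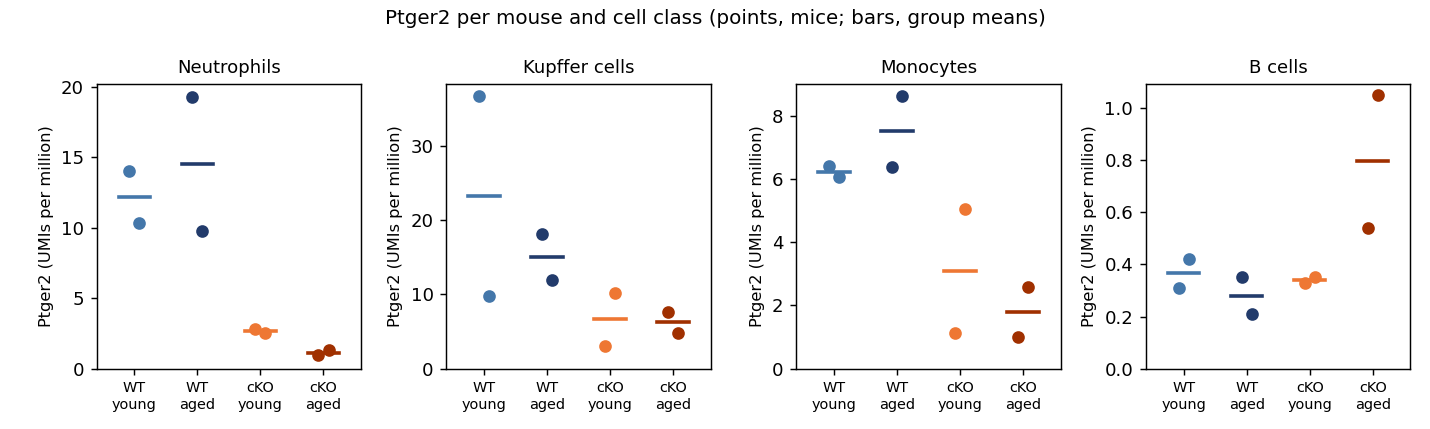
Ptger2 CPM (from raw counts of the class) in neutrophils, Kupffer cells, monocytes and B cells, on separate vertical scales, with 1 point per mouse and a bar at each group mean (2 mice per group). The neutrophils of the 4 cKO mice lie between 0.95 and 2.82 CPM and those of the 4 WT mice between 9.76 and 19.32.

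In Kupffer cells Ptger2 was lower on average in cKO mice, and the unthinned shares of the mice overlapped. The share of Kupffer cells with a Ptger2 UMI was 3.43%, 4.05%, 1.79% and 5.05% in the cKO mice and 13.7%, 4.41%, 17.9% and 5.21% in the WT mice. With cells thinned to 2000 UMIs they did not overlap, at 1.30%, 1.25%, 0.241% and 1.30% in the cKO and 4.90%, 1.67%, 7.67% and 2.25% in the WT mice, from 1 to 7 and 6 to 24 cells with a UMI. The log2 fold change was −1.39 ± 0.715 in aged cKO against aged WT (adjusted p = 0.999 by edgeR), −1.84 ± 0.727 in young cKO against young WT (adjusted p = 1) and −1.64 ± 0.488 in all cKO against all WT mice (adjusted p = 0.922). The Kupffer cells of each mouse held 8 to 74 Ptger2 UMIs. In monocytes the log2 fold change was −1.48 ± 0.462 in all cKO against all WT mice (adjusted p = 0.475). Conventional dendritic cells of type 1, which carried the gene in the highest share of cells among these classes, had it in 11.3% to 16.7% of cells in cKO and 17.4% to 32.3% in WT mice. They were not thinned, and had a median of 11974 to 15417 UMIs per cell against 3724.5 to 8172 in Kupffer cells. By CPM from raw counts, they had 14.28 to 27.55 and Kupffer cells 9.75 to 36.64 in WT mice. In T cells Ptger2 was not lower in cKO mice (0.63 ± 0.307, adjusted p = 0.562). The labels do not say whether the reads counted lie in the deleted part of the gene.

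The 3 genes past the threshold between all cKO and all WT neutrophils in edgeR all fell, and all lie outside the naming rule and were chosen after their values had been seen. The antisense gene Gm17173 fell by 3.95 ± 0.325 on the log2 scale (adjusted p = 0.00658), from 8.64 to 14.97 CPM in the WT mice to 0.455 to 1.17 in the cKO mice. It lies on the minus strand of chromosome 14 at 44972268 to 45006900 and covers all 15626 bp of Ptger2, on the plus strand at 44988195 to 45003820. The gene 4930431P03Rik, 26868 bp away from Ptger2, fell by 5.13 ± 0.571 (adjusted p = 0.0414). Gm16894, which is not annotated near Ptger2, fell by 2.01 ± 0.233 (adjusted p = 0.0414). On the other side Txndc16 and Gpr137c gave 0.18 and 0.19 in neutrophils. Gm49180, 52676 bp away on that side, could be tested only in T cells, where it gave 2.66 ± 0.579 (adjusted p = 0.202). Cadm4 (−3.17 ± 0.484) and Cc2d2a (−2.80 ± 0.428) did not pass (adjusted p = 0.115). DESeq2 called 126 genes and 1097 had an unadjusted p under 0.05 in edgeR. The edgeR count was 15 without WT_Young_2, 5 without WT_Aged_2, 0 without cKO_Young_2 and 1 without any other single mouse.

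Monocytes made up 16.1% ± 0.232 (SD, n = 2) of the immune cells in aged WT and 4.38% ± 2.01 in young WT mice. The log2 ratio of their share was 1.88 ± 0.610 (adjusted p = 0.0824 by edgeR over 12 classes), and 2.18 ± 0.616 in aged cKO against young cKO mice (adjusted p = 0.0814). Aged cKO mice had 26.6% ± 12.6 monocytes, with a log2 ratio of 0.72 against aged WT (adjusted p = 0.847). Kupffer cells made up 3.39% ± 0.565 in aged WT and 2.99% ± 0.735 in young WT mice (log2 ratio 0.18, adjusted p = 0.920) and 3.12% ± 0.356 in aged cKO mice (log2 ratio −0.12 against aged WT, adjusted p = 0.848). Without WT_Young_1 the first of these ratios was −0.05, and without WT_Aged_2 the second was 0.06. Neutrophils made up 39.2% ± 22.1 in young WT, 19.9% ± 16.9 in aged WT, 22.9% ± 3.15 in young cKO and 18.0% ± 3.89 in aged cKO mice. Their log2 ratio was −0.98 ± 0.748 in aged WT against young WT (adjusted p = 0.671) and −0.15 ± 0.741 in aged cKO against aged WT (adjusted p = 0.848), the latter 1.18 without WT_Aged_2 and 0.06 without cKO_Aged_2. With TMM over the classes, the Kupffer ratio of aged to young WT was −0.19, and the ratios of aged cKO to aged WT were 0.47 for Kupffer cells and 0.42 for neutrophils.

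Proliferating cells had the smallest p in aged WT against young WT mice, with 8.52% ± 10.5 against 0.494% ± 0.021, a log2 ratio of 4.11 ± 1.20 (adjusted p = 0.0824 by edgeR). In WT_Aged_2, 52.21% of that class lay in a cluster led by the granulocyte progenitor genes Elane, Prtn3, Fcnb and Mpo, and 44.64% in one led by Prtn3, Mpo, Mki67 and Top2a, against at most 4.81% and 27.88% in any other mouse. The first of these clusters had all 6 markers of proliferation detected (score 0.89, and 0.475 for neutrophils), but none of them is among its 10 leading genes. Without WT_Aged_1, which leaves WT_Aged_2 alone in its group, the log2 ratio of that class was 5.01, and −3.42 in aged cKO against aged WT mice. With all mice, 0 classes passed in any of the 5 contrasts.

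**Figure D2:**
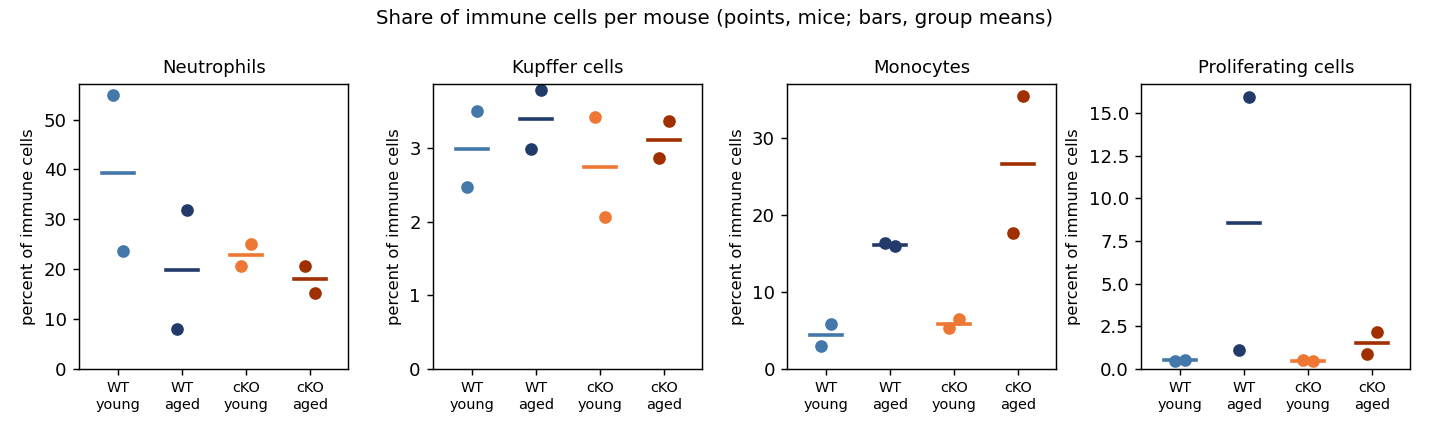
Percent of immune cells per mouse that are neutrophils, Kupffer cells, monocytes or proliferating cells, on separate vertical scales, with 1 point per mouse and a bar at each group mean (2 mice per group). Monocyte shares of the 4 aged mice lie above those of the 4 young mice, and 1 aged WT mouse has 15.95% in the class named proliferating cells. In that mouse 52.21% of the class lie in a cluster led by granulocyte progenitor genes.

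Ageing of WT Kupffer cells showed its smallest p in Saa3, which encodes an acute-phase protein made by macrophages. It had 88 UMIs in the aged and 0 in the young WT mice, at least 23.1-fold higher against a floor of 3 counts over the group (adjusted p = 0.501 by edgeR). Timd4, which encodes a phosphatidylserine receptor for apoptotic cells carried by resident Kupffer cells, was at 163 ± 34.7 CPM (SD, n = 2) in aged and 457 ± 78.3 in young WT mice, with a log2 fold change of −1.49 ± 0.277 (adjusted p = 0.509). Fam13a (−1.94 ± 0.301) and Igfbp1 (−4.86 ± 0.750), the latter a product of hepatocytes, had an adjusted p of 0.501. The engulfment receptors Mertk (0.11, adjusted p = 0.903) and Axl (0.22, adjusted p = 0.840) and the chemokine receptor Cx3cr1 (0.27, adjusted p = 0.843) differed less. No gene of the 11116 tested passed in edgeR, while 895 had an unadjusted p under 0.05 and DESeq2 called 36. Without WT_Aged_2, 77 genes passed.

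Of the gene lists in that comparison, camera called those for cell cycle and ribosomal proteins higher in aged WT Kupffer cells, and those for hepatocyte transcripts, cAMP and CREB, and cholesterol efflux lower. Cell-cycle genes were higher in 13 of 14, with a median log2 fold change of 1.04 (camera adjusted p = 0.0153, and 0.906 with an estimated correlation), but not past the threshold without WT_Aged_2 (0.0764) or WT_Young_1 (0.394). Ribosomal proteins were higher in 23 of 27 (camera adjusted p = 0.00365, and 0.906 with an estimated correlation), and 0.505 without WT_Aged_1. Hepatocyte transcripts, whose RNA may reach other droplets as free RNA, were lower in 14 of 16 with a median of −1.61 (camera adjusted p = 0.00107, and 0.906 with an estimated correlation), and 0.0764 without WT_Aged_2. Genes induced by cAMP and CREB were lower in 9 of 14 (camera adjusted p = 0.0375, reversed at 0.204 without WT_Aged_1 and 0.298 without WT_Young_2), and genes of cholesterol efflux and sterol metabolism in 13 of 15 (0.0377, and 0.0997 without WT_Aged_1 and 0.535 without WT_Young_2), both at 0.906 with an estimated correlation. The list for efferocytosis and engulfment, the removal of dying cells, had 14 of 25 genes higher and a positive median of 0.11, while camera gave the opposite sign (adjusted p = 0.94), with 1 fallen gene when adjusted over the list alone. In none of the lists did a gene pass over all genes. In all comparisons of all classes, camera gave 215 calls, of which 0 held with an estimated correlation and 12 with fry.

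Between aged cKO and aged WT Kupffer cells the smallest p was that of Rsad2, which encodes an antiviral protein induced by interferon. Rsad2 was higher in aged cKO than in aged WT cells by a log2 fold change of 1.93 ± 0.390 (adjusted p = 0.999 by edgeR). The mitochondrial genes mt-Nd4l (−1.26 ± 0.256) and mt-Nd6 (−1.17 ± 0.251) were lower, and Timd4 was higher (0.81 ± 0.273), each with an adjusted p of 0.999. Mertk (−0.10), Axl (0.19) and Cx3cr1 (0.54) also had an adjusted p of 0.999. Interferon-response genes were higher in 26 of 28, with a median log2 fold change of 0.40 and 1 gene past the threshold adjusted over the list alone (camera adjusted p = 2.48e-06, and 0.841 with an estimated correlation). B cell and plasma cell transcripts were higher in 12 of 12 (camera adjusted p = 0.00118, and 0.841 with an estimated correlation), but not past without WT_Aged_2 (0.114) or cKO_Aged_1 (0.517). Lysosome and phagosome genes were higher in 23 of 29 (camera adjusted p = 0.00773, and 0.841 with an estimated correlation), but not past without cKO_Aged_2 (0.387) or WT_Aged_2 (0.301). Efferocytosis genes were higher in 10 of 25 (camera adjusted p = 0.852). No gene passed in edgeR, 340 had an unadjusted p under 0.05 and DESeq2 called 0. Without WT_Aged_2, 3 genes passed.

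In young Kupffer cells the smallest p-values between cKO and WT mice were those of Ly6d (1.63 ± 0.286), a surface protein of B cell precursors, of the calcium channel gene Cacna1e (1.74 ± 0.312) and of mt-Nd4l (−1.28 ± 0.256), all with an adjusted p of 1 by edgeR. Mertk was lower (−0.56 ± 0.247) and Timd4 was not (−0.07). Antigen-presentation genes of MHC class II were higher in 10 of 10 (camera adjusted p = 1.83e-05, and 0.0973 with an estimated correlation). So were B cell and plasma cell transcripts, in 12 of 12 with 10 past the threshold adjusted over the list alone (camera adjusted p = 1.83e-14, and 0.326 with an estimated correlation). In aged cKO against young cKO mice, Saa3 had 250 against 2 UMIs, a ratio of 78.1 (21.4 to 649). The cytokine receptor genes Il7r (−1.67 ± 0.292), also a marker of T and NK cells, and Il6st (−1.33 ± 0.262) were lower, and Timd4 was at −0.61 ± 0.271, with an adjusted p of 0.805 for each of these genes. Interferon-response genes were higher in 28 of 28 (camera adjusted p = 1.55e-08, and 0.45 with an estimated correlation). Genes induced by cAMP and CREB, the pathway downstream of EP2, were lower in 13 of 14 with 4 past the threshold adjusted over the list alone (camera adjusted p = 1.38e-05, and 0.574 with an estimated correlation). So were genes of dissociation and heat shock in 15 of 18 (0.00904, 0.45 with an estimated correlation, 0.131 without cKO_Young_1), B cell and plasma cell transcripts in 11 of 12 (1.38e-05, 0.606 and 0.135 without cKO_Aged_2) and hepatocyte transcripts in 14 of 16 (0.0028, 0.827 and reversed at 0.98 without cKO_Aged_2). In neither comparison did edgeR call a gene (0 and 0), with 294 and 628 at an unadjusted p under 0.05, and DESeq2 called 1 in each.

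Tested directly, the difference between the age effects of cKO and WT Kupffer cells was largest by p in Flt3 (−4.58 ± 0.925), a receptor of dendritic cell precursors, Fam13a (1.79 ± 0.415) and Cacna1e (−1.53 ± 0.435), each with an adjusted p of 1 by edgeR. Timd4 had 0.88 ± 0.384 (adjusted p = 1) and Ptger2 had 0.45 ± 1.02. In edgeR 0 genes passed, 117 had an unadjusted p under 0.05, and DESeq2 called 0. Without WT_Aged_2, 2 genes passed. Across 11116 genes, which are not independent replicates, the age changes of cKO and WT Kupffer cells had r = 0.630 (rho = 0.602), against 0.003 ± 0.014 (SD) in 50 simulated sets without any change. That r was 0.171 without cKO_Aged_2, 0.267 without WT_Aged_1, and 0.505 to 0.614 without any other mouse. These 2 mice are the ones with 95.42% and 99.04% of their Kupffer cells in a cluster that held at most 0.95% in any other mouse, and the simulated sets had no such cluster. The age change in WT and the genotype change in aged mice had r = −0.460 (rho = −0.375), but they share the aged WT mice, and simulated sets without any change gave −0.496 ± 0.014.

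With 4 aged against 4 young mice, Kupffer cells changed in 14 genes, 5 up and 9 down. Saa3 had 338 against 2 UMIs, a ratio of 117 (32.2 to 972, adjusted p = 0.0104 by edgeR). Ptgs2, which encodes the cyclooxygenase that makes the precursor of prostaglandin E2, fell by 1.92 ± 0.254 on the log2 scale, in 4 of 4 aged mice (adjusted p = 0.0480). At the same adjusted p, Csf1, a growth factor of macrophages, fell by 1.76 ± 0.275, the complement regulator Cd55 by 1.58 ± 0.221, the immediate-early gene Egr1, also on the dissociation list, by 1.29 ± 0.185, and the cytokine receptors Il7r, also a marker of T and NK cells, by 1.69 ± 0.234 and Il6st by 1.15 ± 0.178. Ptgs2, Csf1 and Egr1 also lead a neutrophil cluster, which held 1314 to 2280 cells in each young and 38 to 1198 in each aged mouse. Pik3ip1 (−1.97) and Dpy19l1 (−1.44) fell too, and Smo (3.96 ± 0.576), the transducer of Hedgehog signals, and the interferon-induced Gbp8 (1.15 ± 0.176) rose. Timd4 did not pass (−0.99 ± 0.245, adjusted p = 0.138), and neither did Mertk (0.31, adjusted p = 0.425). Genes induced by cAMP and CREB were lower in 12 of 14 (camera adjusted p = 0.000376, and 0.712 with an estimated correlation), with Cd55 past the threshold over all genes and 1 gene when adjusted over the list alone. The 14 genes were among 1978 with an unadjusted p under 0.05, and DESeq2 called 331. The edgeR count was 0 without called doublets, 0 with strict cell limits and 0 with the fit of 4 groups averaged (1628, 988 and 1699 at an unadjusted p under 0.05). It was 1 with replicate number as a block, 2 with genotype as a covariate, 14 with DESeq2 size factors, 17 with the filter against free RNA and 117 with no filter on low counts. Hepatocyte transcripts were lower in 14 of 16 (camera adjusted p = 0.00021, and 0.712 with an estimated correlation). Leaving out 1 mouse gave an edgeR count of 153 without cKO_Aged_1, 129 without WT_Aged_2, 7 without WT_Young_1, 5 without cKO_Young_1, 1 without cKO_Aged_2 or WT_Aged_1, and 0 without cKO_Young_2 or WT_Young_2.

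In neutrophils, ageing of WT mice raised Ffar2, a receptor for short-chain fatty acids, by a log2 fold change of 4.44 ± 0.554 and Gpr84, a receptor for medium-chain fatty acids, by 3.03 ± 0.325 (adjusted p = 0.0377 and 0.0357 by edgeR). Pnp (2.26), Slc31a2 (1.98), Treml2 (1.77) and Cyfip1 (1.38) rose as well. Among fallen genes were Thbs1 (−3.44 ± 0.440), a matrix protein and target of CREB, the phosphodiesterase gene Pde3b (−2.96 ± 0.320), Vopp1 (−2.40), the phosphatase gene Ptpn22 (−2.29), Ralgapa1 (−2.11), Arl15 (−1.71) and the acid-sensing receptor gene Gpr65 (−1.47), at adjusted p-values of 0.0357 to 0.0396. The senescence marker Cdkn1a was lower (−1.74 ± 0.304, adjusted p = 0.0692) and did not pass. Neither did the chemokine receptors Cxcr4 (−1.04, adjusted p = 0.304) and Cxcr2 (0.27, adjusted p = 0.567) or S100a8 (1.14, adjusted p = 0.231). Granule protein genes were higher in 16 of 16, with a median of 3.42, 0 past the threshold over all genes and 14 adjusted over the list alone (camera adjusted p = 5.68e-05, and 0.731 with an estimated correlation). In WT_Aged_2, 25.96% of the neutrophils lay in a cluster led by the granule genes Ltf, Ngp and Camp and 68.15% in one led by Prok2, Ly6g, Retnlg and Mmp8, against at most 2.26% and 6.74% in any other mouse. Hepatocyte (15 of 16, camera adjusted p = 1.26e-06) and endothelial transcripts (13 of 14, 0.00376) were lower, both at 0.731 with an estimated correlation. In all 40 genes passed, 8 up and 32 down, among 3090 with an unadjusted p under 0.05, and DESeq2 called 967. The count was 24 with strict cell limits and 0 with replicate number as a block (2977 at an unadjusted p under 0.05). It was 2236 without WT_Aged_1, 409 without WT_Aged_2, 2 without WT_Young_1, 1 without cKO_Aged_1 or cKO_Aged_2, and 0 without cKO_Young_1, cKO_Young_2 or WT_Young_2.

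Between aged cKO and aged WT neutrophils, the antisense gene Gm17173, outside the naming rule, had a smaller p than Ptger2 (3.06e-05 against 3.45e-05 by edgeR). It fell by 4.27 ± 0.481 (adjusted p = 0.149) and was picked after its values had been seen. Among genes that the rule allows, the smallest p after Ptger2 were those of 2 genes with an adjusted p of 0.284. They were the copper transporter gene Slc31a2 (−1.71 ± 0.236) and Cc2d2a (−3.32 ± 0.473), a gene of the primary cilium. Cdkn1a was higher (0.77 ± 0.298, adjusted p = 0.363), as was Cxcr4 (1.23 ± 0.577, adjusted p = 0.411). S100a8 (−0.76, adjusted p = 0.545) and Cxcr2 (0.01, adjusted p = 0.993) did not pass. Granule protein genes were lower in 16 of 16 with a median of −2.29 (camera adjusted p = 0.00114, and 0.635 with an estimated correlation), but without WT_Aged_2 the direction reversed (0.181). Transcripts of hepatocytes (15 of 16, 9.37e-06), endothelial (13 of 14, 0.000306), mesenchymal (10 of 11, 0.000358), B and plasma (11 of 12, 0.00838), Kupffer (9 of 10, 0.034) and erythroid cells (5 of 5, 0.0345) were higher by camera, all at 0.635 with an estimated correlation. Without WT_Aged_2 they were at 0.051 (hepatocyte), 0.288 (mesenchymal) and 0.944 (erythroid, and Kupffer with a reversed direction), and B and plasma cell transcripts were at 0.365 without cKO_Aged_1. Without cKO_Aged_2 the Kupffer list also reversed (0.827) and the erythroid one was at 0.548. The neutrophil-ageing list had 7 of 13 genes higher (camera adjusted p = 0.102). With edgeR 0 genes passed, 1677 had an unadjusted p under 0.05 and DESeq2 called 87. The count was 863 without WT_Aged_1 and 32 without WT_Aged_2.

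Over all aged against all young mice, neutrophils gained Ccr2, a chemokine receptor (log2 fold change 2.30 ± 0.324), the G-protein regulator Rgs3 (1.72 ± 0.211), Treml2 (1.47), Rap1gap2 (1.28), Bin2 (1.26) and Mdh2 (0.86). Jade1 (−1.61) and Eepd1 (−1.24) were among the genes they lost, at adjusted p-values of 0.0357 to 0.0487 by edgeR. Interferon-response genes were higher in 28 of 28 with a median of 1.66, 0 past the threshold over all genes and 23 adjusted over the list alone (camera adjusted p = 3.85e-09, and 0.670 with an estimated correlation). A cluster led by Stfa2l1, Slfn4, Rsad2 and Oasl2 held 72.32% of the neutrophils of cKO_Aged_2, 46.59% in WT_Aged_1, 14.39% in cKO_Aged_1, 4.29% in WT_Aged_2 and 1.3% to 6.59% in the young mice. Kupffer (10 of 10, camera adjusted p = 0.0395, and 0.508 without cKO_Aged_2) and platelet transcripts (6 of 6, 0.0323, and 0.118 without cKO_Aged_2) were higher and hepatocyte transcripts lower (15 of 16, 8.72e-06), at 0.783, 0.696 and 0.670 with an estimated correlation. In all 10 genes passed, 6 up and 4 down, among 3102 with an unadjusted p under 0.05, and DESeq2 called 1145. The count was 1070 without cKO_Aged_1, 273 without WT_Aged_2 and 0 without any other single mouse.

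Monocytes of aged WT mice lost Zbtb16, a transcription factor of innate-like lymphocytes and myeloid progenitors, with a log2 fold change of −2.42 ± 0.178 (adjusted p = 0.00423 by edgeR). Fhit (−2.36 ± 0.249), a tumour suppressor gene, and Dnah12 (−2.12 ± 0.221), an axonemal dynein gene, had an adjusted p of 0.0282, and the lipid transporter gene Abca6 (−1.83 ± 0.202) had 0.0306. Dnah12 also leads a monocyte cluster, with Ace, Adgre4 and Ear2. That cluster held 22.6% and 12.62% of the monocytes in the aged WT and 27.76% and 35.1% in the young WT mice. Zbtb16, Fhit, Dnah12 and Abca6 were all the genes past the threshold, among 1423 with an unadjusted p under 0.05, and DESeq2 called 151. The count was 0 with strict cell limits (1051 at an unadjusted p under 0.05) and 1 with replicate number as a block. It was 160 without WT_Aged_2, 12 without WT_Aged_1, 2 without WT_Young_1, 1 without cKO_Young_1 or cKO_Young_2 and 0 without WT_Young_2. Between aged cKO and aged WT monocytes, the protease inhibitor gene Serpinb1a (−1.17 ± 0.205), Tex14 (−1.36 ± 0.248) and Zbtb16 (0.86 ± 0.171) had the smallest p, with an adjusted p of 0.848. No gene (0) passed there in edgeR, 719 had an unadjusted p under 0.05 and DESeq2 called 3, and the count was 17 without WT_Aged_2 and 3 without WT_Aged_1. Patrolling-monocyte genes were higher in 10 of 10 (camera adjusted p = 0.00251, and 0.715 with an estimated correlation), though 0.336 without WT_Aged_2. The cluster led by Ace, Dnah12, Adgre4 and Ear2 held 27.46% and 28.07% of the monocytes in the aged cKO against 22.6% and 12.62% in the aged WT mice. A change within monocytes was not separated from this mix. Hepatocyte transcripts were higher in 15 of 16 (camera adjusted p = 1.19e-06), endothelial in 13 of 14 (4.03e-05) and B and plasma cell transcripts in 12 of 12 (0.000353), all at 0.715 with an estimated correlation. None held in every omission, with hepatocyte at 0.108 and B and plasma cell transcripts at 0.0961 without cKO_Aged_1 and endothelial at 0.194 without WT_Aged_1.

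Over all aged against all young mice, monocytes gained Saa3 (log2 fold change 4.37 ± 0.538, adjusted p = 0.0416 by edgeR), the histone genes H1f5 (1.49) and H2bc4 (1.35), and B3gnt8 (1.25). They lost the haemoglobin scavenger receptor Cd163 (−2.76 ± 0.360, adjusted p = 0.0344), Tns1 (−2.22), Zbtb16 (−1.81), Id2 (−1.18) and Ralgps1 (−1.17). Cd163 also leads a Kupffer cluster. Cd209b, a lectin of marginal-zone macrophages, had 1 UMI in the aged against 36 in the young mice, a ratio of 0.00655 (0.000161 to 0.0389, adjusted p = 0.0237). Genes of oxidative phosphorylation were higher in 34 of 36 (camera adjusted p = 8.13e-06, and 0.665 with an estimated correlation), and hepatocyte transcripts were lower in 15 of 16 (1.99e-07 and 0.665). In all 16 genes passed, 4 up and 12 down, among 2166 with an unadjusted p under 0.05, and DESeq2 called 427. The count was 6 with strict cell limits and 1 with replicate number as a block. It was 327 without cKO_Aged_1, 47 without WT_Young_1, 3 without WT_Aged_2, 1 without WT_Aged_1 and 0 without cKO_Aged_2 or any of the other young mice.

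In endothelial cells, ageing of WT mice gave its smallest p in the clock gene Nr1d2 (−2.04 ± 0.207, adjusted p = 0.195 by edgeR), followed by the chemerin receptor gene Ccrl2 (−1.65 ± 0.215) and Zfp521 (1.46 ± 0.185), with an adjusted p of 0.370. Over all aged against all young mice Nr1d2 (−1.56 ± 0.197), Ccr2 (1.39 ± 0.164) and Jade2 (−1.11 ± 0.140) had an adjusted p of 0.0646. Interferon-response genes were then higher in 25 of 28, 14 of them past the threshold adjusted over the list alone and 0 over all genes (camera adjusted p = 6.58e-07, and 0.852 with an estimated correlation), and hepatocyte transcripts (14 of 16, 4.09e-06) and genes of dissociation and heat shock (13 of 18, 0.0185, and 0.127 without WT_Aged_2) were lower, both at 0.852. The lists for sinusoidal identity (camera adjusted p = 0.736) and capillarization, the loss of sinusoidal pores (0.575), did not pass. Between aged cKO and aged WT mice, Rsad2 (1.24 ± 0.206), Csrnp1 (0.89 ± 0.162) and Iqcn (−2.53 ± 0.464) had an adjusted p of 0.839. Lysosome genes were higher in 28 of 29 in that comparison (camera adjusted p = 1.12e-05, and 0.712 with an estimated correlation). So were hepatocyte transcripts in 15 of 16 (7.86e-06, and 0.427 without cKO_Aged_1) and genes of dissociation and heat shock in 13 of 18 (0.017, and 0.459 without WT_Aged_2), while neutrophil transcripts were lower in 12 of 14 (0.0123, reversed at 0.039 without WT_Aged_2), all at 0.712 with an estimated correlation. By edgeR 0 genes passed in aged WT against young WT, in aged cKO against aged WT and in all aged against all young mice, with 1381, 828 and 2130 at an unadjusted p under 0.05, and DESeq2 called 114, 0 and 389. The first count was 3 without cKO_Aged_1 or cKO_Aged_2 and 2 without WT_Aged_1, the second was 51 without cKO_Aged_1, and the third was 155 without cKO_Aged_1 and 24 without cKO_Aged_2. The third was also 2 with replicate number as a block, 5 with strict cell limits and 16 with the filter against free RNA.

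In T cells, ageing of WT mice raised Gzmk, a granzyme of memory and effector CD8 T cells, by a log2 fold change of 3.09 ± 0.265 and Rap1gap2 by 1.48 ± 0.122 (adjusted p = 0.0173 by edgeR). Pik3ip1, an inhibitor of PI3K kept by resting T cells, fell by 1.45 ± 0.152 and mt-Nd3 by 2.49 ± 0.269 (adjusted p = 0.0466). These 4 were all the genes past the threshold, among 3184 with an unadjusted p under 0.05, and DESeq2 called 692. The count was 136 without cKO_Aged_1, 134 without cKO_Aged_2, 23 without WT_Aged_2, 13 without WT_Aged_1, 2 without WT_Young_1 and 0 without WT_Young_2. Between aged cKO and aged WT T cells the smallest p-values were those of the phosphatase gene Dusp1 (1.16 ± 0.124, adjusted p = 0.127), Trf (1.38 ± 0.206) and Mid2 (1.96 ± 0.295), the last 2 with an adjusted p of 0.279. There 0 genes passed in edgeR, 1663 had an unadjusted p under 0.05 and DESeq2 called 102.

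Over all aged against all young mice, T cells lost genes of naive cells and gained genes of effector and exhausted cells. The transcription factors of naive T cells Lef1 (−1.13 ± 0.132, adjusted p = 0.00446 by edgeR), Bach2 (−1.38 ± 0.153) and Tcf7 (−0.93 ± 0.130) fell in 4 of 4 aged mice, as did Il6ra (−1.07 ± 0.084), Nsg2 (−1.31), Klhl6 (−1.66), Maml3 (−1.29), Kif1b (−1.13) and Pik3ip1 (−1.46 ± 0.096, adjusted p = 0.000315). Of the naive-cell list, 9 of 11 genes fell and 11 did when adjusted over the list alone (camera adjusted p = 8e-11, fry 0.000711, and 0.0918 with an estimated correlation). A cluster led by Lef1, Tcf7 and Nsg2 held 22.91% to 31.66% of the T cells of the young and 2.49% to 11.33% of those of the aged mice. The inhibitory receptors Pdcd1 (1.80 ± 0.411, adjusted p = 0.0377) and Tigit (0.92 ± 0.151, adjusted p = 0.0116) and the ectonucleotidase gene Entpd1 (0.36) rose, with 8 of 11 genes of the exhaustion list past the threshold and 10 adjusted over the list alone (fry 0.00968, and 0.187 with an estimated correlation). The cytotoxic genes Nkg7 (1.12 ± 0.184, adjusted p = 0.0116), Cst7 (1.02) and Tbx21 (0.66) rose, with 6 of 18 listed genes past the threshold and 14 adjusted over the list alone (fry 0.00665, and 0.155 with an estimated correlation). Gzmk, named for its rise in WT, rose by 1.94 ± 0.422 (adjusted p = 0.0354). So did Cdk1 (1.90), Cenpf (1.96) and Top2a (1.38) of the cell cycle, Isg15 (2.16), Irf7 (0.76) and Rtp4 (1.00) of the interferon response, and Cdkn2a (2.16 ± 0.354, adjusted p = 0.0115), which encodes the senescence marker p16. Saa3 (3.79 ± 0.475), H1f5 (2.49), Ica1 (1.62), Rap1gap2 (1.32), Acot7 (0.86) and Zdhhc2 (0.83) rose too, and Igfbp4 fell (−1.83). Saa3 also rose in Kupffer cells and monocytes. Kupffer (10 of 10, camera adjusted p = 0.0289, and 0.141 without cKO_Aged_2) and platelet transcripts (6 of 6, 0.0289, and 0.0614 without cKO_Young_1) were higher and hepatocyte transcripts lower (15 of 16, 3.93e-06), at 0.607, 0.607 and 0.402 with an estimated correlation. In all 1340 genes passed, 732 up and 608 down, and DESeq2 called 2475. The count was 586 with strict cell limits. It was 2628 without cKO_Aged_1, 987 without WT_Aged_2, 1033 without WT_Young_1, 433 without WT_Aged_1, 430 without cKO_Young_1, 400 without cKO_Aged_2, 181 without cKO_Young_2 and 139 without WT_Young_2.

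**Figure D3:**
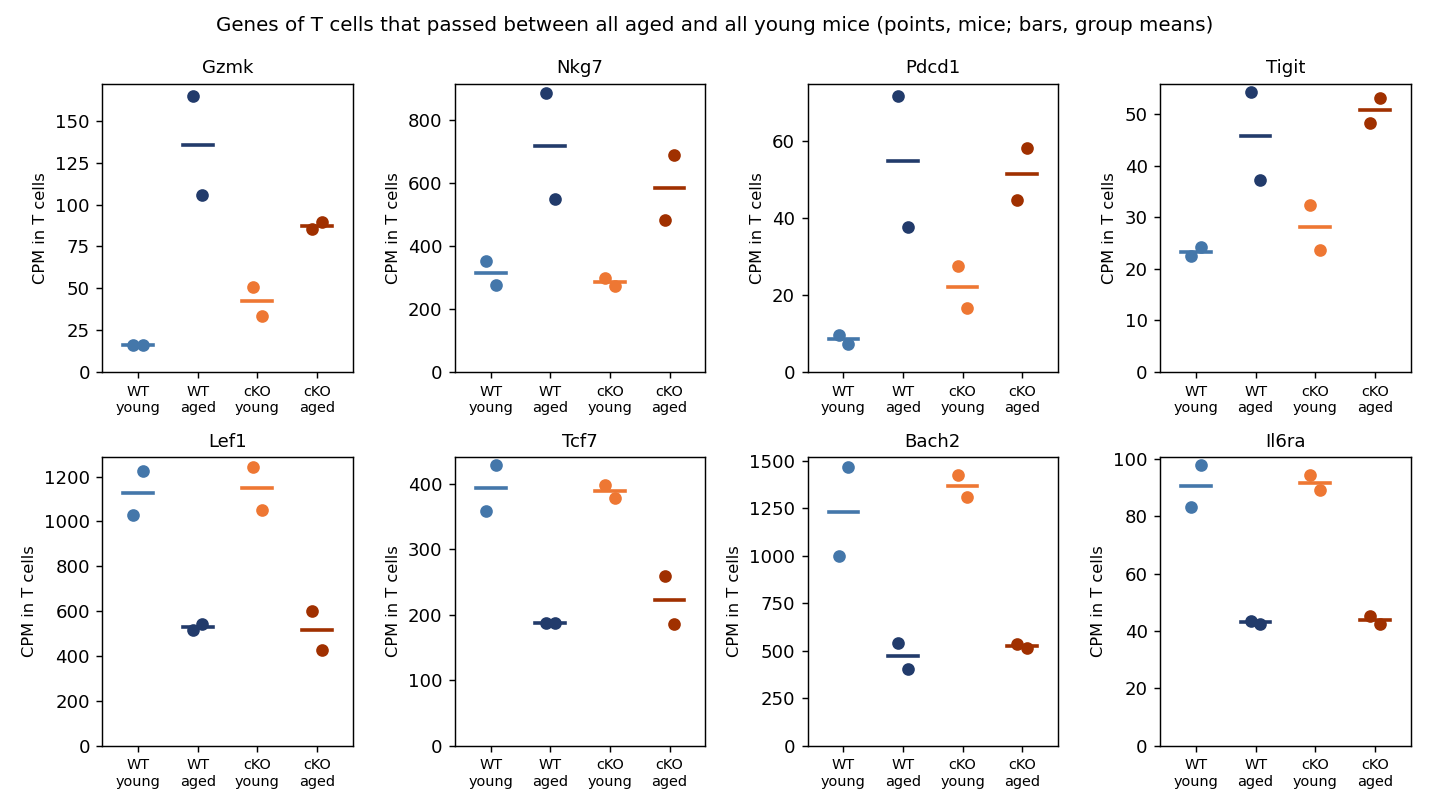
CPM in T cells of 8 genes that passed between all aged and all young mice, on separate vertical scales, with 1 point per mouse and a bar at each group mean (2 mice per group). The upper 4 genes are higher and the lower 4 genes are lower in all aged than in all young mice.

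In B cells the comparison of aged WT with young WT mice gave its smallest p-values in mt-Nd3 (−2.36 ± 0.234), mt-Nd4l (−1.44 ± 0.185) and the histone gene H2az1 (0.85 ± 0.108), with an adjusted p of 0.0504 by edgeR. Although 0 genes passed in edgeR, 3207 had an unadjusted p under 0.05 and DESeq2 called 840. The edgeR count was 1 with strict cell limits, 101 with replicate number as a block, 553 with the filter against free RNA and 1870 with no filter on low counts. It was 595 without WT_Aged_2, 43 without WT_Young_1, 13 without WT_Aged_1 and 1 without any of the 4 cKO mice. Aged cKO against aged WT B cells showed a fall of Lmna (−2.06 ± 0.188), which encodes lamin A, of the actin-binding protein gene Tagln2 (−1.48 ± 0.138) and of Vim (−1.21 ± 0.117), which encodes vimentin (adjusted p = 0.0153). These 3 were all the genes past the threshold, among 2244 with an unadjusted p under 0.05, and DESeq2 called 196. The count was 225 without WT_Aged_2, 6 without WT_Aged_1, 2 without cKO_Young_1 or cKO_Young_2 and 0 without any of the other mice. Genes of age-associated B cells were higher in 11 of 13 (camera adjusted p = 1.06e-05, and 0.654 with an estimated correlation), though 0.444 without WT_Aged_1. Hepatocyte (16 of 16, 0.000189, and 0.193 without cKO_Aged_1) and endothelial transcripts (14 of 14, 1.06e-05, and 0.162 without WT_Aged_1) were higher as well, both at 0.654 with an estimated correlation.

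Over all aged against all young mice, B cells gained Pycard, the adaptor of inflammasomes (log2 fold change 1.22 ± 0.112, adjusted p = 0.00617 by edgeR), the peroxidase gene Gpx1 (0.92 ± 0.102, adjusted p = 0.00819), Ankrd37 (1.55), Lppos (1.74), Prelid1 (0.76) and the plasma-cell chaperone gene Mzb1 (1.15 ± 0.148, adjusted p = 0.0101). The immunoproteasome genes Psmb8 (1.20), Psmb9 (1.00) and Psmb10 (1.05) rose, as did 8 of 14 genes of MHC class I presentation, 10 adjusted over the list alone (fry 0.0194, and 0.465 with an estimated correlation). Of the interferon response, Isg15 (1.68), Ifi27l2a (1.17) and Xaf1 (0.94) were among 7 of 28 genes that rose and 20 adjusted over the list alone (fry 0.0228, and 0.465 with an estimated correlation). Oxidative phosphorylation had 18 genes up, with Cycs (0.72), Cox6b1 (0.49) and Atp5g1 (0.68) among them, and 1 down of 36, 27 and 1 adjusted over the list alone (fry 0.0194, and 0.465 with an estimated correlation). The mitochondrially encoded mt-Nd1 (−1.17 ± 0.144) and mt-Nd4 (−1.22 ± 0.153) fell, as did Herc4 (−0.86), Mcmdc2 (−2.07), Pabpc1l (−2.48), Sgk3 (−0.80) and Dusp1 (−0.77). The median mitochondrial share of B cells was 5.83% to 7.91% in the aged and 11.64% to 15.94% in the young mice. The glycolysis genes Gapdh (0.72), Pgam1 (0.71) and Tpi1 (0.92), the class II genes H2-Ab1 (0.41) and H2-Eb1 (0.51), and the cell-cycle inhibitor gene Cdkn2d (0.64) rose. Bmp2 (−1.37) of endothelial cells and Il7r (−1.40) and Nkg7 (1.18) of T and NK cells also passed. Hepatocyte transcripts were lower in 15 of 16 (camera adjusted p = 1.91e-06, and 0.465 with an estimated correlation). In all 1050 genes passed, 711 up and 339 down, and DESeq2 called 2136. The count was 130 with strict cell limits, 93 up and 37 down. It was 1360 without cKO_Aged_1, 965 without WT_Young_1, 925 without WT_Aged_1, 584 without WT_Aged_2, 453 without cKO_Aged_2, 219 without cKO_Young_1, 44 without WT_Young_2 and 1 without cKO_Young_2.

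In the comparison of all cKO with all WT mice outside neutrophils, Iqcn, a gene of the axoneme and sperm, was the 1 gene past the threshold in B cells, with a log2 fold change of −2.60 ± 0.232 (adjusted p = 0.00904 by edgeR) and 0.940 to 1.30 CPM in the 4 cKO against 5.62 to 8.78 in the 4 WT mice. In B cells 1540 genes had an unadjusted p under 0.05 and DESeq2 called 238. The B cell count was 45 without WT_Young_2, 0 without cKO_Aged_1, cKO_Young_1, cKO_Young_2 or WT_Young_1, and 1 without any of the other mice. Kupffer cells had their smallest p-values in mt-Nd4l (−1.27 ± 0.231), Tecpr2 (−0.84 ± 0.167), an autophagy gene, and mt-Nd6 (−1.02 ± 0.205), with an adjusted p of 0.922. Monocytes had them in Tex14 (−1.12 ± 0.188), the NF-kB regulator gene Nfkbid (0.93 ± 0.162) and Timd4 (2.16 ± 0.369), with an adjusted p of 0.302. Timd4 also leads a Kupffer cluster, and camera called the Kupffer transcripts in monocytes there, though not without WT_Aged_1 (adjusted p = 0.0505). Endothelial cells had Iqcn (−2.19 ± 0.306) and Hs3st3b1 (−0.55 ± 0.086) at an adjusted p of 0.488, and Havcr2 (0.91 ± 0.157) at 0.570. T cells had the glutathione transferase gene Gstm1 (1.58 ± 0.174) and the deacetylase gene Hdac9 (1.28 ± 0.160) at an adjusted p of 0.0940, and Tulp2 (−1.46 ± 0.207) at 0.125. By edgeR 0 genes passed in Kupffer cells, monocytes, endothelial cells and T cells, with 591, 1000, 1005 and 1517 at an unadjusted p under 0.05, and DESeq2 called 15, 51, 24 and 220. Only the T cell count moved when 1 mouse was left out, to 1 without WT_Aged_1. It was also 11 with age as a covariate, 5 with the fit of 4 groups averaged and 1 with strict cell limits, which gave 1 in monocytes too. Lysosome genes of Kupffer cells were higher in 25 of 29 cKO over WT (camera adjusted p = 0.000142, and 0.546 with an estimated correlation), as were B cell and plasma cell transcripts in 12 of 12 (1.08e-09 and 0.600) and genes of dissociation and heat shock in 16 of 18 (0.00913 and 0.600, and 0.115 without cKO_Young_1).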

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

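All tests in this part were planned, and none was chosen after the result was seen. Among the shares of immune cells, 3 mice lay far from the other mice of their age. Monocytes made up 35.48% of the immune cells of cKO_Aged_2, the highest of the 4 aged mice. Proliferating cells made up 15.95% in WT_Aged_2, also the highest of the 4 aged mice, with 52.21% of them in a cluster led by the granulocyte progenitor genes Elane, Prtn3, Fcnb and Mpo. Neutrophils made up 54.89% in WT_Young_1, the highest of the 4 young mice. In each case the gap to the nearest mouse, divided by the range of the 4, was above Dixon's critical value of 0.829. With 24 such tests, chance gives about 1 in 20. No explanation was tested for these 3 shares.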

How the results depend on the processing

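The tests chosen after the result was seen are the alternatives of both comparisons of 4 mice against 4, including the other factor as a covariate and the averaged 4-group model, and those of the list counts in young genotype, cKO ageing and the difference of age effects in Kupffer cells and of Ptger2 in aged neutrophils. Results are named here as WT ageing (aged WT against young WT), cKO ageing, aged genotype (aged cKO against aged WT), young genotype, ageing over all mice and genotype over all mice, and values are counts of genes past the threshold unless stated. The cause was not tested for any change given here, except that leaving out a mouse also leaves fewer samples. Size factors of DESeq2 kept 32 results on the comparisons and all 131 named genes in direction and call, and moved 1 count, that of monocytes in ageing over all mice, to 26. Removal of called doublets kept 36 results and 118 named genes, ended the call of 13 genes, and moved the Kupffer count of ageing over all mice to 0. Using all cells as the total kept all 6 share results.

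Without a filter on low counts the counts rose in most comparisons. Kupffer cells had 544 (WT ageing), 122 (aged genotype), 59 (young genotype), 329 (cKO ageing), 43 (the difference of age effects) and 117 (ageing over all mice). Neutrophils had 1933 (WT ageing), 879 (aged genotype), 255 (ageing over all mice) and 14 (genotype over all mice). Monocytes had 644 (WT ageing), 331 (aged genotype) and 158 (ageing over all mice). Endothelial cells had 880 (WT ageing), 374 (aged genotype) and 61 (ageing over all mice). T cells had 848 (WT ageing), 138 (aged genotype) and 2 (genotype over all mice). B cells had 1870 (WT ageing), 1087 (aged genotype) and 16 (genotype over all mice). The Wald test of DESeq2 also gave other counts. Kupffer cells gave 36 (WT ageing), 1 (young genotype), 1 (cKO ageing), 331 (ageing over all mice) and 15 (genotype over all mice). Neutrophils gave 967 (WT ageing), 87 (aged genotype), 1145 (ageing over all mice) and 126 (genotype over all mice). Monocytes gave 151 (WT ageing), 3 (aged genotype), 427 (ageing over all mice) and 51 (genotype over all mice). Endothelial cells gave 114 (WT ageing), 389 (ageing over all mice) and 24 (genotype over all mice). T cells gave 692 (WT ageing), 102 (aged genotype), 2475 (ageing over all mice) and 220 (genotype over all mice). B cells gave 840 (WT ageing), 196 (aged genotype), 2136 (ageing over all mice) and 238 (genotype over all mice).

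With an estimated correlation camera called 0 lists in each of the 27 class and contrast combinations, and 215 list calls ended. Fry called 2 lists in T cells in WT ageing and 4 in ageing over all mice, 6 of the 8 that camera called in B cells in ageing over all mice, and 0 in the other combinations, and kept 12 of the 215 calls. With the replicate number as a block the gene counts were Kupffer cells 1 (ageing over all mice), neutrophils 0 (WT ageing), monocytes 1 (WT ageing) and 1 (ageing over all mice), endothelial cells 2 (ageing over all mice), T cells 12 (WT ageing), B cells 101 (WT ageing) and 5 (aged genotype). List counts moved in monocytes, to 8 (WT ageing) and 15 (ageing over all mice).

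With strict cells the counts were Kupffer cells 0 (ageing over all mice), neutrophils 24 (WT ageing) and 53 (ageing over all mice), monocytes 0 (WT ageing), 6 (ageing over all mice) and 1 (genotype over all mice), endothelial cells 5 (ageing over all mice). The same setting gave T cells 21 (WT ageing), 586 (ageing over all mice) and 1 (genotype over all mice), B cells 1 (WT ageing), 5 (aged genotype), 130 (ageing over all mice) and 5 (genotype over all mice). The free-RNA filter gave neutrophils 109 (ageing over all mice), monocytes 33 (ageing over all mice), endothelial cells 16 (ageing over all mice), T cells 42 (WT ageing), B cells 553 (WT ageing), 51 (aged genotype) and 18 (genotype over all mice). With the other factor as a covariate the counts were Kupffer cells 2 (ageing over all mice), neutrophils 10 (genotype over all mice), monocytes 31 (ageing over all mice), T cells 11 (genotype over all mice), B cells 107 (genotype over all mice). The averaged 4-group model gave Kupffer cells 0 (ageing over all mice), neutrophils 119 (ageing over all mice) and 1 (genotype over all mice), T cells 832 (ageing over all mice) and 5 (genotype over all mice), B cells 68 (genotype over all mice). TMM over the immune classes reversed 3 of 6 shares, with log2 ratios of −0.19 for Kupffer cells in WT ageing, 0.47 for Kupffer cells in aged genotype and 0.42 for neutrophils in aged genotype. Over genes with a mean CPM of at least 50, the correlation of the age changes of cKO and WT Kupffer cells was 0.752.

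Leaving out 1 mouse at a time moved the gene counts over wide ranges, and the mouse whose omission gave the highest count is named in parentheses. Kupffer cells ranged from 0 to 3 for aged genotype (WT_Aged_2), 0 to 77 for WT ageing (WT_Aged_2), 0 to 153 for ageing over all mice (cKO_Aged_1) and 0 to 2 for the difference of age effects (WT_Aged_2). Neutrophils ranged from 0 to 863 for aged genotype (WT_Aged_1), 0 to 2236 for WT ageing (WT_Aged_1), 0 to 1070 for ageing over all mice (cKO_Aged_1) and 0 to 15 for genotype over all mice (WT_Young_2). Monocytes ranged from 0 to 17 for aged genotype (WT_Aged_2), 0 to 160 for WT ageing (WT_Aged_2) and 0 to 327 for ageing over all mice (cKO_Aged_1). Endothelial cells ranged from 0 to 51 for aged genotype (cKO_Aged_1), 0 to 3 for WT ageing (cKO_Aged_1) and 0 to 155 for ageing over all mice (cKO_Aged_1). T cells ranged from 0 to 136 for WT ageing (cKO_Aged_1), 139 to 2628 for ageing over all mice (cKO_Aged_1) and 0 to 1 for genotype over all mice (WT_Aged_1). B cells ranged from 0 to 225 for aged genotype (WT_Aged_2), 0 to 595 for WT ageing (WT_Aged_2), 1 to 1360 for ageing over all mice (cKO_Aged_1) and 0 to 45 for genotype over all mice (WT_Young_2). The counts of called lists moved as well. Kupffer cells had 5 to 15 for aged genotype (WT_Aged_1), 6 to 16 for cKO ageing (cKO_Aged_1), 5 to 8 for WT ageing (WT_Aged_1), 6 to 14 for ageing over all mice (cKO_Aged_1), 5 to 11 for genotype over all mice (WT_Aged_1), 5 to 12 for the difference of age effects (cKO_Aged_1) and 6 to 11 for young genotype (cKO_Young_1). Neutrophils had 8 to 17 for aged genotype (WT_Aged_1) and 4 to 12 for genotype over all mice (WT_Aged_1). Monocytes had 8 to 15 for aged genotype (WT_Aged_1), 3 to 13 for WT ageing (WT_Aged_2) and 3 to 15 for ageing over all mice (cKO_Aged_1). Endothelial cells had 4 to 9 for WT ageing (WT_Aged_1) and 5 to 8 for ageing over all mice (WT_Aged_2). T cells had 4 to 12 for genotype over all mice (WT_Aged_1). B cells had 5 to 10 for aged genotype (cKO_Aged_1) and 1 to 8 for genotype over all mice (WT_Aged_2). The count of immune classes past the threshold was 0 to 1 in WT ageing (cKO_Aged_1, cKO_Aged_2 and WT_Aged_1) and in aged genotype (WT_Aged_1). The log2 ratio of the Kupffer share was −0.047 (without WT_Young_1) to 0.46 in WT ageing and −0.283 to 0.059 (without WT_Aged_2) in aged genotype, and that of the neutrophil share −0.826 to 1.18 (without WT_Aged_2) in aged genotype, and 0.059 without cKO_Aged_2. The log2 fold change of Ptger2 in neutrophils in aged genotype was −4.07 (without WT_Aged_2) to −3.24 (without WT_Aged_1). The correlation across genes was 0.171 (without cKO_Aged_2) to 0.614 between both age changes, and −0.738 to −0.132 (without cKO_Aged_1) between WT ageing and aged genotype.

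For 25 gene lists at least 1 omission reversed the direction, and their camera adjusted p is given as the range over the omissions, with the value at each reversal. B cells in genotype over all mice had endothelial markers 0.000338 to 0.325 (reversed without WT_Aged_1 at 0.325). Kupffer cells in WT ageing had cAMP-CREB response 5.85e-06 to 0.298 (reversed without WT_Aged_1 at 0.204). Kupffer cells in aged genotype had oxidative phosphorylation 2.18e-10 to 0.387 (reversed without cKO_Aged_2 at 0.387). Kupffer cells in cKO ageing had cell cycle 4.72e-06 to 0.98 (reversed without cKO_Aged_2 at 0.98), glycolysis 3.59e-06 to 0.922 (reversed without cKO_Aged_2 at 0.922), hepatocyte markers 2.67e-06 to 0.98 (reversed without cKO_Aged_2 at 0.98) and oxidative phosphorylation 1.15e-05 to 0.0667 (reversed without cKO_Aged_2 at 0.0574). Kupffer cells in the difference of age effects had ribosomal proteins 2.63e-13 to 0.587 (reversed without cKO_Aged_1 at 0.587). T cells in aged genotype had cytotoxic effector 0.000377 to 0.784 (reversed without WT_Aged_1 at 0.784), glycolysis 1.22e-07 to 0.601 (reversed without cKO_Aged_2 at 0.601) and interferon response 2.36e-10 to 0.816 (reversed without WT_Aged_2 at 0.816 and cKO_Aged_2 at 0.177). T cells in genotype over all mice had endothelial markers 0.000326 to 0.562 (reversed without WT_Aged_1 at 0.562). Endothelial cells in aged genotype had glycolysis 4.81e-07 to 0.303 (reversed without cKO_Aged_2 at 0.303), interferon response 1.03e-15 to 0.915 (reversed without WT_Aged_2 at 0.915), neutrophil markers 1.33e-13 to 0.303 (reversed without WT_Aged_2 at 0.039) and senescence and SASP 6.53e-05 to 0.9 (reversed without cKO_Aged_2 at 0.9). Monocytes in WT ageing had oxidative phosphorylation 2.51e-15 to 0.277 (reversed without WT_Aged_1 at 0.277). Monocytes in aged genotype had interferon response 1.08e-11 to 0.234 (reversed without WT_Aged_2 at 0.234) and platelet markers 2.24e-08 to 0.909 (reversed without cKO_Aged_2 at 0.909). Monocytes in genotype over all mice had platelet markers 0.0071 to 0.506 (reversed without cKO_Aged_2 at 0.506). Neutrophils in WT ageing had MHC class I presentation 1.65e-13 to 0.61 (reversed without WT_Aged_1 at 0.61). Neutrophils in aged genotype had neutrophil granule proteins 1.33e-14 to 0.181 (reversed without WT_Aged_2 at 0.181), Kupffer markers 6.13e-10 to 0.944 (reversed without WT_Aged_2 at 0.944 and cKO_Aged_2 at 0.827) and oxidative phosphorylation 0.00247 to 0.967 (reversed without WT_Aged_2 at 0.967). Neutrophils in genotype over all mice had neutrophil granule proteins 0.00115 to 0.617 (reversed without WT_Aged_2 at 0.617).

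Of all values without 1 mouse, 373 results on the comparisons, 576 on named genes and 1452 on lists kept direction and call, while 472 gene calls and 241 list calls ended without a change of direction. In the simulated 2 against 2 comparison, Kupffer cells, at 317 to 568 cells per mouse, had 3% of the genes changed 2-fold recovered, neutrophils 13.4% and monocytes 20.9%, and depth was not separated there from the spread between mice.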

Other observations

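The tests chosen after the result was seen in this part are the B cell value for free RNA and the observed against expected UMIs for Ptger2, and the values given here for Iqcn, Gm17173 and the clusters were also picked after they had been seen. Iqcn was lower in cKO than in WT mice in all 6 classes, with log2 fold changes of −3.08 in Kupffer cells, −2.67 in T cells, −2.60 in B cells, −2.19 in endothelial cells, −1.95 in monocytes and −1.21 in neutrophils, of which only that in B cells passed over all genes. Gm17173, antisense to Ptger2, was at −2.99 in Kupffer cells, −2.60 in monocytes, −2.14 in endothelial cells, −1.39 in T cells and −1.20 in B cells, none past the threshold in edgeR (adjusted p of 0.221 to 0.922). In T and B cells Ptger2 itself was not lower (0.63 and 0.65). The labels do not say whether WT and cKO mice differ at loci other than Ptger2.

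The mice of a group differed in the clusters their cells fell into. Of the Kupffer cells, 99.04% in WT_Aged_1 and 95.42% in cKO_Aged_2 were in 1 cluster that held at most 0.95% of them in any other mouse. Neutrophils of WT_Aged_2 were 25.96% in the cluster led by Ltf, Ngp and Camp (at most 2.26% elsewhere) and 68.15% in that led by Prok2 and Ly6g (at most 6.74%). A T cell cluster led by Gzmk, Cd8a and Pdcd1 held 45.32% of the T cells of WT_Aged_1, 17.08% to 28.3% in the other aged mice and 3.62% to 14.06% in the young mice. A B cell cluster led by Ebf1, Ighd and Cr2 held 70.19% to 83.06% of the B cells of the young and 2.12% to 29.02% of those of the aged mice, and one led by Cr2, Fcer2a, Bank1 and Ccr6 held 73.27% to 78.26% in 3 aged mice, 18.54% in cKO_Aged_1 and 1.62% to 14.8% in the young mice.

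Ptger2 was lower in cKO than in WT neutrophils in 4 of 4 mice, in animals whose deletion was driven by Cx3cr1. Free RNA lower in cKO livers would lower Ptger2 in B cells too, if these do not express it themselves. There its log2 fold change was 0.652 ± 0.526, from only 1 to 13 UMIs per mouse. A difference in depth per cell is argued against by neutrophils thinned to 2000 UMIs, where the highest cKO share was 0.605% and the lowest WT share 1.75%. For a different mix of clusters, the first test, within 1 cluster, could not tell, because WT_Aged_2 had 38 cells and 0 UMIs there (highest cKO mouse 2.84 CPM), and the second argues against it, with observed over expected UMIs of at most 0.212 in cKO and at least 0.639 in WT mice. A candidate explanation is deletion in a cell that gives rise to neutrophils, which no test here addressed, and the place of the counted reads in the gene stays open.

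The T cell genes called between all aged and all young mice numbered 1340, but 2628 without cKO_Aged_1, 433 without WT_Aged_1, 430 without cKO_Young_1, 400 without cKO_Aged_2, 181 without cKO_Young_2 and 139 without WT_Young_2. Among cells with 5 to 10% mitochondrial UMIs, 1288 of the 1340 could be measured and their log2 fold changes had a slope of 0.885 on those in all cells, with 374 genes called in both. Young cells there still had a higher mean mitochondrial share, 8.10% to 8.75% against 6.50% to 7.10%. Within 1 T cell cluster, the slope was 0.734 over 1205 genes, 97.4% of which kept their sign, and 21 genes were called in both. That cluster held 19.24% to 53.31% of the T cells of a mouse. Its mean mitochondrial shares were 5.71% to 7.35% in the aged and 10.51% to 14.43% in the young mice. Both slopes lie above the bound of 0.5 set for them. The first argues against the mitochondrial share as the whole cause and the second against the mix of clusters for that cluster alone. The mix stays open for the other T cells, and the share and the mix were not held fixed together. An effect of age may remain as a hypothesis, with handling of the age groups at different times open.

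The B cell genes called between all aged and all young mice were weighed with the same tests. With 5 to 10% mitochondrial UMIs the slope was 0.843 over 1020 of the 1050 genes, with 142 called in both, and the young mice had means of 8.38% to 8.76% against 6.59% to 7.45%. Within 1 B cell cluster, led by Sox5, Fcrl5 and Bhlhe41 and holding only 2.85% to 25.17% of the B cells of a mouse, it was 0.758 over 962 genes, 98% with the same sign and 48 called in both. The first argues against the mitochondrial share as the whole cause and the second against the mix of clusters for that subset alone, so that the mix stays open for most B cells. Without cKO_Young_2 the count was 1, without WT_Young_2 44, without cKO_Young_1 219, without cKO_Aged_2 453 and without WT_Aged_2 584, so that an effect of age may be a hypothesis only.

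The 8 mice can be split 4 against 4 in 35 ways. Only the real split by age reached its count in T cells (1340 genes, 1 split, at most 1 in any other), in B cells (1050, 1 split, at most 1) and in neutrophils (10, 1 split, at most 3). That is the smallest share of 35 splits possible, and it lies under 0.05 only without adjustment over the classes and comparisons tested. With such an adjustment 35 splits are too few to exclude chance for these 3. The neutrophil count was also 0 without any mouse but cKO_Aged_1 (1070) or WT_Aged_2 (273). Nor can chance be excluded for ageing in Kupffer cells (14 genes, 2 splits, at most 23 in another) and monocytes (16, 2 splits, at most 25). There the split with more genes was that by age with cKO_Aged_1 and WT_Young_1 exchanged. For genotype in neutrophils (3, 2 splits) and in B cells (1, 2 splits) the only other split that reached the count was the one by age (10 and 1050), and every split besides these gave 0 genes, so that the number of splits does not decide there. With 0 genes called by edgeR, all 35 splits gave as many for genotype in Kupffer cells (591 at an unadjusted p under 0.05, 15 by DESeq2, at most 23 in another split), monocytes (1000, 51, at most 25), endothelial cells (1005, 24, at most 0) and T cells (1517, 220, at most 1340 in the split by age), and for ageing in endothelial cells (2130, 389, at most 0). Age thus separates the T and B cells of these mice by more genes than any other split.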
